A study of Homo sapiens with 4 samples.

How the data were processed

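RNA was sequenced from KMS11, an established cell line of t(4;14) multiple myeloma, in 4 libraries. Per the labels, 2 libraries came from cells given a control shRNA and 2 from cells given an shRNA against NSD2. The lentivirus was added with polybrene at 10 µg/mL, and RNA was taken after 96 h, which included 72 h after a change of medium. Libraries were made with an Illumina TruSeq kit from 1 µg of total RNA. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

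The deposited values in the file of each library are raw fragment counts per Ensembl gene. Per the labels, the authors trimmed the reads with Trim Galore 0.3.7, aligned them to GRCh37 with STAR 2.5.3, used Picard, and counted with featureCounts of Subread 1.4.6. Per the file headers, fragments were counted without regard to strand, from alignments whose names mark the removal of duplicates. The authors also deposited a DESeq2 table whose header names a contrast of M2 over LUC. Its deposited columns are a log2 fold change with its standard error, a Wald statistic (a score), a p-value with its adjusted value, a base mean and the exonic length of each gene in bp. The version of DESeq2 and the libraries in that model are not stated. The 4 count columns of that table were not used, and 1 blank line per count file was left out.

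Each library held 62069 genes. Symbols came from the deposited table, which named 36524 of them, and gene types from GENCODE 29, which matched 50409 by identifier. Coordinates are those of the deposited table, on GRCh37. Total fragments ranged from 46728940 to 55059566 per library.

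The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter of edgeR on low counts and the group as the only term. P-values were adjusted by Benjamini and Hochberg over the 17172 genes tested, and an adjusted p below 0.05 was the threshold. Levels are given as CPM (fragment counts scaled to a common library size) on TMM-scaled libraries, with the SD over the 2 libraries of a group. The coefficient of biological variation was 9.81%. The intervals at 95% rest on this model.

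The gene lists, 35 in number, were fixed before the data were examined, as were the design, the alternative settings and the rule for naming genes. The 32 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, and the p-values were adjusted over those lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the residual degrees of freedom, 2 here and 1 with the replicate block, which by itself raises its p-values. A call lost with it therefore cannot be laid to correlated genes alone. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. The named genes were chosen by rule. It took NSD2, CCND1, PTP4A3, SMARCA2, FGFR3 and LETM1. It took the 12 highest and the 12 lowest log2 fold changes among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. It also took up to 3 members that rose and 3 that fell in each list, by smallest adjusted p. Genes outside the rule are said to have been chosen after their values were seen. A gene that the rule took is not reported here.

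The procedure was tested on simulated counts with the same groups, in which 200 genes were changed and 16876 were tested. Of the tested genes, 65, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. The procedure recovered 56.9% of the 1.5-fold, 77.6% of the 2-fold and 93.9% of the 4-fold changes, with 14 false among 165 calls, and made 0 calls when no gene was changed. The GC content and length terms were tested on another simulation with a GC trend between the groups. There they brought false calls from 6218 among 6386 calls down to 23 among 174, and recovered 75.9% of the changed genes. That simulation had no length trend and as many rises as falls, so it tests neither the length term nor the share of lower calls.

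The alternative settings were RLE, upper-quartile and library-size scaling, no filter and a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom, robust empirical Bayes, a replicate block, a minimum of 2-fold, and leaving out each library. When 1 library was left out, the lone library of its group was assumed to vary like the others. After the data were seen, smooth terms for GC content and exonic length were added, alone and with the block. Ranges of adjusted p over the alternatives leave out the block, and for lists they cover camera with the preset correlation only, so that estimated correlation and fry are given apart. Figures were drawn with matplotlib 3.10.9.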

Results

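Messenger RNA was profiled by RNA sequencing in KMS11, a cell line of multiple myeloma, the cancer of plasma cells, that carries the t(4;14) translocation. Control shRNA was given in 2 libraries and an shRNA against NSD2 in 2. The control libraries held 50417758 and 46728940 counted fragments, and the libraries labelled NSD2 knockdown held 48334736 and 55059566. Mitochondrial genes took 5.89% and 5.86% of the fragments in the control libraries, 5.82% in knockdown library 1 and 6.82% in knockdown library 2.

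The comparison of the libraries labelled NSD2 knockdown with the control libraries asks which transcripts depend on NSD2, a histone methyltransferase gene that the translocation places under an immunoglobulin enhancer. NSD2 itself (ENSG00000109685, chromosome 4, 1873151 to 1983934, GRCh37) stood at 1121 and 1471 CPM in control libraries 1 and 2, and at 919 and 1156 CPM in knockdown libraries 1 and 2. Its mean was 1296 ± 248 CPM (SD, n = 2) in the control libraries and 1037 ± 167 CPM (SD, n = 2) in those labelled knockdown, a difference of 19.9%. The log2 fold change was -0.32 (SE 0.15, 95% interval -0.66 to 0.02, adjusted p = 0.244), and the 2 groups overlapped. NSD2 thus did not pass the test, and the second group is called by its label throughout. FGFR3, the receptor tyrosine kinase gene also affected by the translocation, was at 3959 ± 14.8 against 3397 ± 19.7 CPM (log2 fold change -0.22, adjusted p = 0.224), and LETM1, between FGFR3 and NSD2, was at 57.1 ± 5.15 against 54.3 ± 1.01 CPM (adjusted p = 0.723).

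The log2 ratio of NSD2, knockdown over control, was -0.29 between the libraries numbered 1 and -0.35 between those numbered 2. Number 2 exceeded number 1 by a log2 ratio of 0.39 in the control group and 0.33 in the group labelled knockdown. The labels do not say that equal numbers mark a pair. The log2 fold change of NSD2 moved with the library left out, which such a difference between the numbers would give. It was -0.50 without control library 1 and -0.50 without knockdown library 2, but -0.12 without control library 2 and -0.16 without knockdown library 1. Over all alternatives its adjusted p ran from 0.0173 to 0.833, and with terms for GC content and length, added after the data were seen, its log2 fold change was -0.06.

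PTP4A3, which encodes the phosphatase PRL3 and is named in the title of the series, fell from 162 ± 20.1 to 98.1 ± 12.6 CPM (SD, n = 2 each). This was a fall of 39.6% (chromosome 8, 142402093 to 142441620, log2 fold change -0.73, SE 0.122, 95% interval -1 to -0.45, adjusted p = 0.00887), and both knockdown libraries lay below both controls. CCND1, which encodes the G1 cyclin D1, stood at 33.2 and 44.3 CPM in the control libraries and at 27.9 and 26.0 CPM in those labelled knockdown (chromosome 11, 69455855 to 69469242). Its log2 fold change of -0.52 (SE 0.137, 95% interval -0.83 to -0.22) missed the threshold with an adjusted p of 0.0543. SMARCA2, an ATPase subunit of the SWI/SNF chromatin remodelling complex, was at 208 ± 13.1 and 209 ± 4.27 CPM, with a 95% interval for its log2 fold change of -0.21 to 0.22 (chromosome 9, 2015342 to 2193624). Of these 4 study genes, 1 fell and 0 rose, and 2 were lower when adjusted over the list alone.

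PTP4A3 kept its call under every alternative run, with log2 fold changes from -0.87 to -0.60 when 1 library was left out. CCND1 passed the threshold without control library 1 (log2 fold change -0.71, adjusted p = 6.65e-05) and without knockdown library 1 (-0.57, adjusted p = 0.0124), as well as with DESeq2 (adjusted p = 0.0185). Without control library 2 its log2 fold change was -0.31, and its adjusted p ran from 6.65e-05 to 0.145 over the scalings, filters, tests, GC and length terms and left-out libraries.

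**Figure D1:**
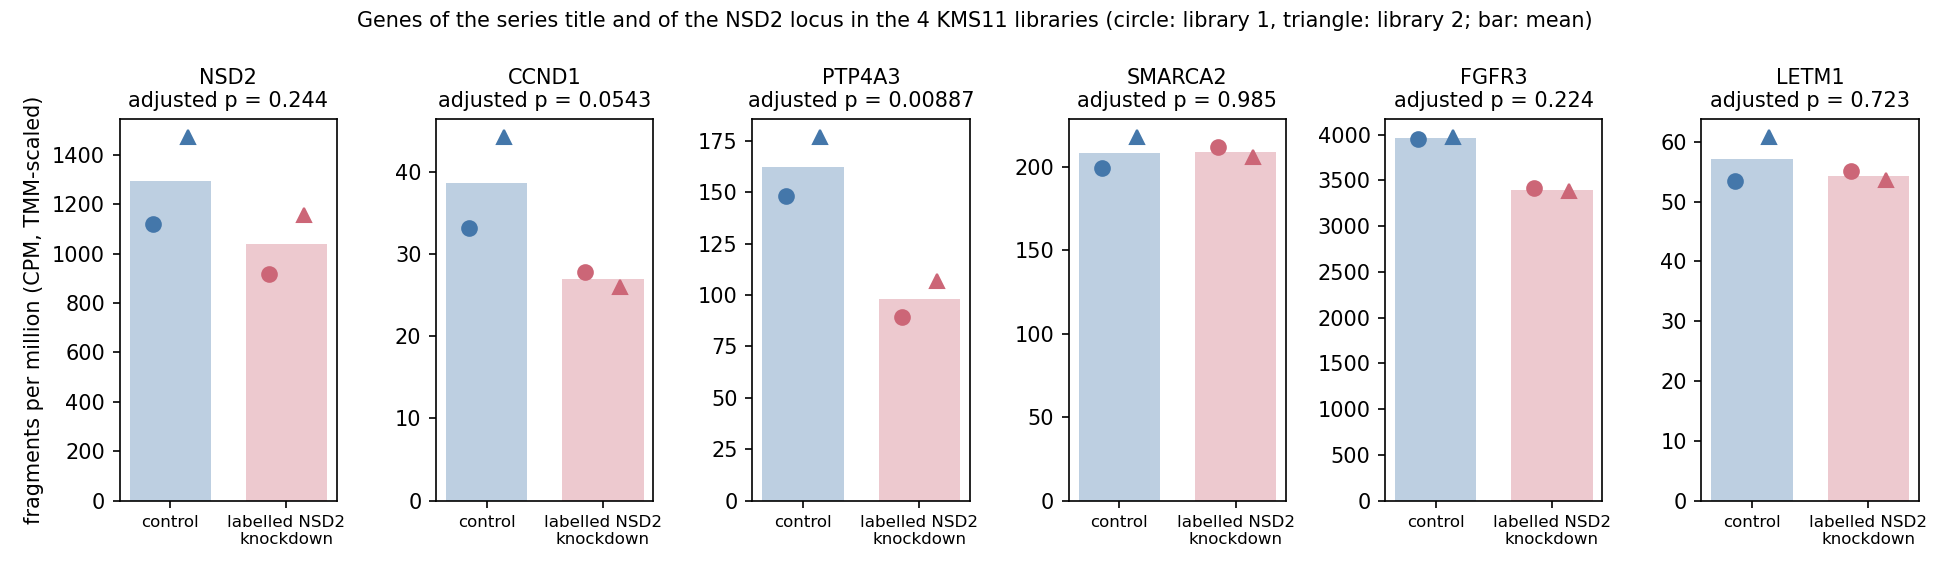
Level of 6 genes in each of the 4 libraries, in TMM-scaled CPM. Points are libraries (circle for library 1, triangle for library 2), bars are group means, and the adjusted p of edgeR stands above each panel. Both points labelled knockdown lie below both control points for CCND1, PTP4A3 and FGFR3, but only PTP4A3 passed the threshold.

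Across the transcriptome, 299 genes were higher and 719 lower in the libraries labelled NSD2 knockdown among 17172 tested, and 931 of these 1018 genes were protein-coding. Among protein-coding genes of at least 5 CPM whose groups did not overlap, the largest rise was that of FRMD3, a gene of the FERM domain family, from 21.2 ± 5.47 to 139.8 ± 54.4 CPM (6.62-fold, chromosome 9, 85857905 to 86153461). COL26A1, which encodes a collagen, rose 5.31-fold, the lipid transporter gene ABCA2 3.85-fold, EGFL7 3.54-fold and the leukocyte integrin gene ITGB2 3.43-fold. CTSB, which encodes the lysosomal protease cathepsin B, rose 3.18-fold from an already high level, from 591 ± 51.3 to 1882 ± 462 CPM. MICALL2, the sodium channel gene SCNN1G, SRPK3, the neutrophil protease gene PRTN3, EMID1 and the IGF-binding protein gene IGFBP4 completed the 12 largest rises, at 3.25-fold down to 2.64-fold.

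By the same measure, the largest fall was that of VIL1, which encodes the actin-bundling protein villin, from 14.1 ± 3.17 to 1.99 ± 0.568 CPM (7.04-fold lower, chromosome 2, 219283815 to 219318018). FBP1, an enzyme gene of gluconeogenesis, was 5.38-fold lower, KLHL29 4.42-fold, the axon guidance receptor gene PLXNA4 3.90-fold and the smooth muscle myosin gene MYH11 3.75-fold. PRSS1 was counted 4.24-fold lower, but trypsinogen genes have near-identical copies, so which copy the fragments came from is uncertain. SEL1L3, FAM84B, HOMER2, the spectrin gene SPTB, SERINC2 and DPYSL3 made up the rest of the 12 largest falls, at 3.43-fold down to 2.92-fold. All 24 genes were past the threshold under each alternative run. Fragments were counted without regard to strand, and 6 of the 24 (ITGB2, SRPK3, VIL1, MYH11, SEL1L3 and FAM84B) overlap another tested gene, so for these the gene of origin is uncertain. The same holds for CCND1, PTP4A3 and SMARCA2 above and, among the genes named by list below, for HLA-DPB1, SELPLG, F11R, CD151, MUC1, IL6R, ETV4, CCNE2, ALDH1L2, FADS1, STARD4 and TNRC6C.

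These calls come from edgeR, with 3865 genes at an unadjusted p below 0.05, and the groups did not overlap in 53.2% of genes, where chance gives 33.3%. The counts also changed when 1 library was left out. Such a fit has 1 library in a group and takes its spread from the other group alone. Its counts therefore do not show how far the calls depend on that library. The same limit holds for every gene or list call given here from such a fit.

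**Figure D2:**
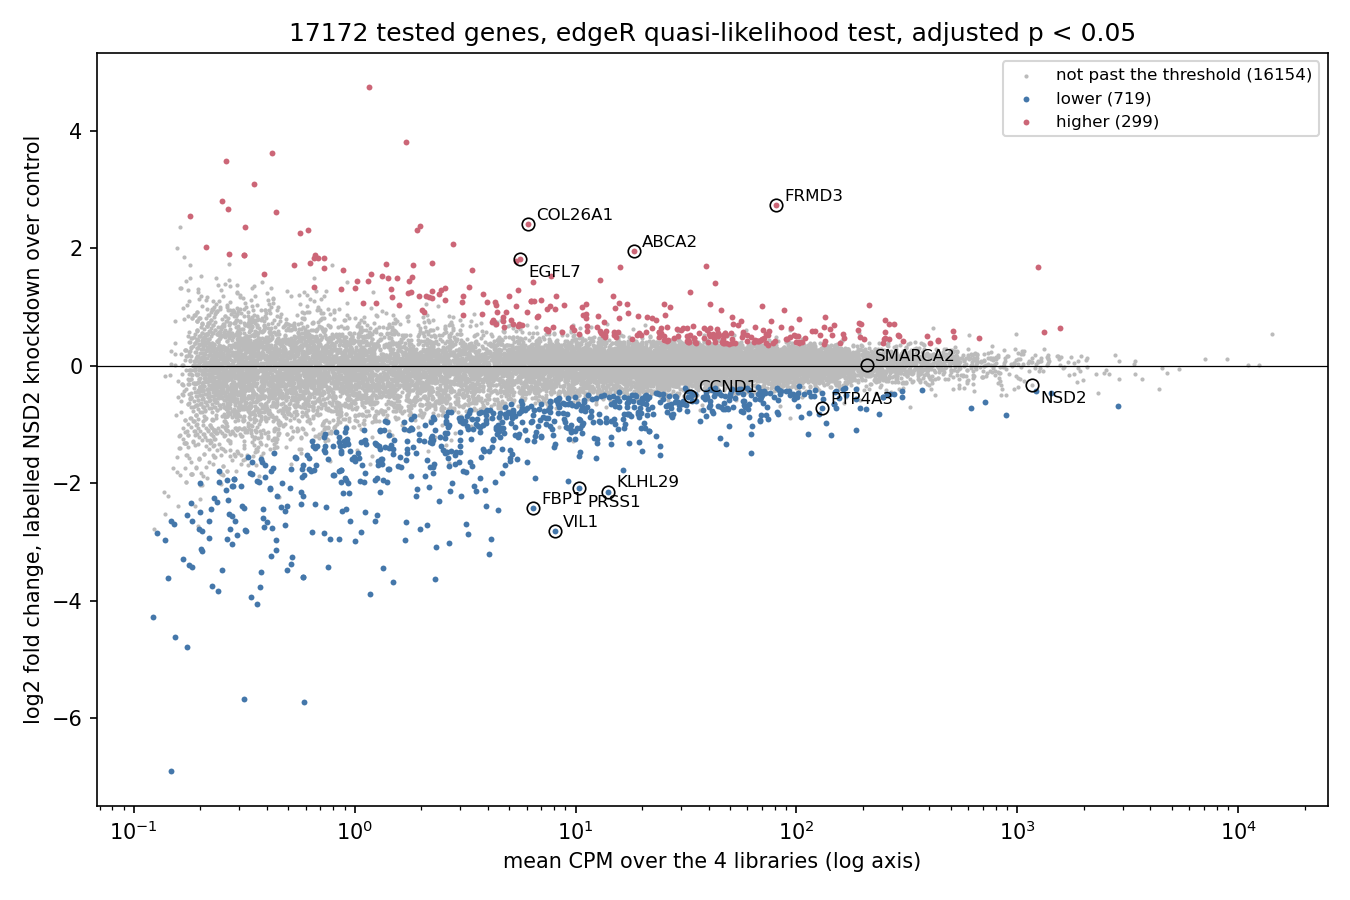
Log2 fold change of each of the 17172 tested genes (vertical axis, libraries labelled NSD2 knockdown over control) against its mean level in CPM over the 4 libraries (horizontal log axis). Coloured points are the 299 higher and 719 lower genes, and circled points are named genes. FRMD3 lies at a log2 fold change of 2.73 and VIL1 at -2.82, while NSD2 lies at -0.32 among the highly expressed genes.

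The MHC class II part of the B cell programme fell. Of 20 tested members, 7 fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone. All 7 falls were those of class II genes or of their activator gene, as was seen only from the values. HLA-DRA, a class II antigen-presenting chain, fell from 1135 ± 103 to 636 ± 66.1 CPM (log2 fold change -0.84, adjusted p = 0.00354). HLA-DMB, which helps to load peptides on class II, fell with a log2 fold change of -0.99 and HLA-DPB1 with -1.03, though fragments of HLA genes can be shared between related copies. The single rise was that of the B cell receptor gene CD79B, from 40.8 ± 1.98 to 59.9 ± 5.38 CPM, which was not past the threshold without knockdown library 2 (log2 fold change 0.45, adjusted p = 0.0652). The list was lower by camera (adjusted p = 0.0225), but adjusted p = 0.876 with an estimated correlation, and the call was lost without control library 1 (adjusted p = 0.153, range 0.00631 to 0.153 over the alternatives). Among plasma cell identity genes, 5 of 25 fell and 0 rose (0 rose and 7 fell adjusted over the list alone). SLAMF7, a surface receptor of plasma cells, fell from 254 ± 25.2 to 119 ± 13.4 CPM (2.14-fold, adjusted p = 0.000952), ITM2C fell 1.53-fold and the caveolin gene CAV1 1.88-fold. Camera did not call this list in the main fit (adjusted p = 0.0924). It called the list with the replicate block, alone (adjusted p = 0.0422) and with GC and length terms (0.0344), and without knockdown library 2. With the block and an estimated correlation the adjusted p of camera was 0.849. More members of the list fell without control library 1.

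Adhesion molecules moved in both directions, with more falls than rises. Of 43 tested members, 13 fell and 4 rose, and 17 fell and 4 rose when adjusted over the list alone. The neural adhesion gene NCAM1 fell from 2.14 ± 0.279 to 0.339 ± 0.0412 CPM (log2 fold change -2.64), SELPLG, the ligand of P-selectin, fell from 240.8 ± 7.56 to 145 ± 1.26 CPM (-0.73) and the junction gene F11R fell with -0.78. The integrin chain gene ITGA8 rose from 19.4 ± 2.02 to 46.5 ± 1.91 CPM (2.40-fold), alongside ITGB2 and the tetraspanin gene CD151 (1.45-fold). Camera placed the list lower (adjusted p = 0.0164), but adjusted p = 0.876 with an estimated correlation, and without knockdown library 1 it was 0.0539 (range 0.0111 to 0.0539).

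Some epithelial genes fell in this plasma cell line. Of 8 tested members of a list of epithelial and kidney line markers, 4 fell and 0 rose, over all genes and adjusted over the list alone. The mucin gene MUC1 fell from 27.6 ± 4.11 to 11.2 ± 2.10 CPM (2.46-fold), the keratin gene KRT18 fell 2.97-fold from 3.96 ± 0.18 CPM, and EPCAM fell from 52.4 ± 9.58 to 30.6 ± 1.83 CPM. The list was lower by camera (adjusted p = 0.00184), including without any single library, but adjusted p = 0.566 with an estimated correlation. HOX genes, the homeobox regulators of body patterning, gave 3 falls and 0 rises among 13 tested members (4 falls and 0 rises adjusted over the list alone). HOXC4 had 21 and 23 fragments in the control libraries against 2 and 1 in those labelled knockdown, although its span overlaps that of HOXC5 and HOXC6. HOXC13 fell from 1.46 ± 0.261 to 0.376 ± 0.0933 CPM. Camera called the HOX list lower (adjusted p = 0.00158), also without any single library, but adjusted p = 0.566 with an estimated correlation. Most HOX genes were near the detection limit, with a median of 0.461 CPM in the control libraries.

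Interferon-stimulated genes fell more often than they rose. Of 56 tested members, 6 fell and 1 rose, and 10 fell and 4 rose when adjusted over the list alone. The antiviral synthetase gene OAS2 fell from 22.2 ± 0.21 to 11.2 ± 1.14 CPM (1.98-fold, adjusted p = 0.00222), and its relative OASL fell from 3.49 ± 1.21 to 1.04 ± 0.425 CPM. The single rise, that of IFI44, was not past the threshold without knockdown library 2 (adjusted p = 0.196) nor with upper-quartile scaling, library-size scaling, the stricter filter, limma-voom or GC and length terms. The number of rises was 3 without control library 1, 3 without control library 2 4 without knockdown library 1 and 0 without knockdown library 2. Camera gave an adjusted p of 0.0169 for the list, but adjusted p = 0.566 with an estimated correlation, and 0.121 without knockdown library 1 (range 0.0108 to 0.121).

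Signalling genes downstream of growth factor and cytokine receptors fell in part. In the list of receptor tyrosine kinase and MAPK feedback genes, 5 of 28 tested members fell and 0 rose (8 fell and 0 rose adjusted over the list alone). PHLDA1 fell from 5.93 ± 0.0164 to 2.79 ± 0.2 CPM, and the ETS factor gene ETV4 fell 1.78-fold, a call lost without knockdown library 2 (adjusted p = 0.0515). Of 27 STAT3 target and IL6 signalling genes, 3 fell and 1 rose, over all genes and adjusted over the list alone. MUC1, PTP4A3 and the IL6 receptor gene IL6R fell, the last from 82.1 ± 9.7 to 55.1 ± 1.46 CPM. PTP4A3 was placed in this list by way of the title of the series and is no independent evidence of its direction. The kinase gene PIM1 rose from 145 ± 11.1 to 240 ± 52.1 CPM (log2 fold change 0.73, and 0.49 without knockdown library 2). Of 12 translocation partner and cyclin D genes of myeloma, 2 fell and 0 rose (4 fell and 0 rose adjusted over the list alone). This list holds NSD2, CCND1 and FGFR3, and the MAPK list holds CCND1 and FGFR3, so neither is independent of the genes reported above. MYCL, a relative of MYC, fell from 3.19 ± 0.22 to 1.33 ± 0.0808 CPM.

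Camera called these 3 lists lower with an adjusted p of 0.0345, 0.0342 and 0.0342, but with an adjusted p of 0.566 each with an estimated correlation. The estimated correlations were -0.0223, -0.0369 and -0.0258, below the preset 0.01. Correlated genes therefore do not account for that higher p, and the few residual degrees of freedom can. Leaving out single libraries ended the calls. For the MAPK list the adjusted p was 0.147 without control library 1, 0.0518 without control library 2 and 0.182 without knockdown library 1, and 8 members fell without control library 1, while 1 rose without control library 2 and 2 without knockdown library 1. For the STAT3 list it was 0.139, 0.062, 0.176 and 0.102 without control library 1, control library 2, knockdown library 1 and knockdown library 2. For the myeloma list it was 0.156 without control library 2 and 0.182 without knockdown library 1, and 5, 3 and 3 members fell without control library 1, knockdown library 1 and knockdown library 2. The lowest adjusted p over the alternatives was 0.0154, 0.0313 and 0.0344 for the 3 lists in that order.

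Cell cycle genes showed few changes. Of 47 DNA replication and S phase genes, 2 fell and 0 rose, over all genes and adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell from 773 ± 116 to 467 ± 69.3 CPM (1.65-fold, adjusted p = 0.0137), and the cyclin gene CCNE2 fell from 49.4 ± 4.54 to 36.1 ± 1.89 CPM, a call lost without control library 2 (adjusted p = 0.0579) and without knockdown library 2 (adjusted p = 0.154). Of 34 ATF4 and amino acid response genes, 2 fell and 0 rose (3 fell and 0 rose adjusted over the list alone). The falls were those of ATF3, from 27.2 ± 1.8 to 19.7 ± 0.27 CPM, and of ALDH1L2, an enzyme gene of mitochondrial folate metabolism, from 161 ± 23.9 to 91.3 ± 32.4 CPM. ATF3 lost its call only in fits that left out 1 library. Its log2 fold change there ran from -0.537 to -0.391, against -0.465 with all libraries. The call of ALDH1L2 was fragile: it was lost with library-size scaling, the stricter filter, DESeq2 (adjusted p = 0.259), robust empirical Bayes and GC and length terms. The log2 fold change of ALDH1L2 was -0.82, and -0.51 without knockdown library 2. Camera called the S phase list lower (adjusted p = 0.0169) and the ATF4 list lower (adjusted p = 0.0213), but adjusted p = 0.973 each with an estimated correlation.

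Both list calls were lost without control library 1 or knockdown library 2. Either loss unbalances the library numbers, and number 2 was lower than number 1 in both lists (camera, preset correlation, adjusted p = 1.91e-07 and 5.52e-10). With the replicate block camera kept both calls (adjusted p = 0.00741 and 0.00142), but gave 0.963 and 0.849 with an estimated correlation. The labels do not say that equal numbers mark a pair. The adjusted p of the S phase list was 0.333 without control library 1 and 0.979 without knockdown library 2, and that of the ATF4 list 0.826 and 0.581, with lowest values over the alternatives of 0.000112 and 0.000285. Without control library 1, control library 2 and knockdown library 1, the S phase list held 4, 5 and 8 falls. The ATF4 list held 3, 10, 10 and 3 falls without control library 1, control library 2, knockdown library 1 and knockdown library 2.

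No ribosomal protein gene passed the threshold. Of 82 tested members 0 rose and 0 fell by edgeR, over all genes and adjusted over the list alone, 3 had an unadjusted p below 0.05, and DESeq2 and limma-voom also called 0. Their median log2 fold change was 0.10. Camera called the list higher (adjusted p = 0.00184), but adjusted p = 0.973 with an estimated correlation, and the call was lost without control library 2 (adjusted p = 0.141) and without knockdown library 2 (adjusted p = 0.278, range 3.26e-05 to 0.278). The MYC and ribosome biogenesis list of 46 likewise had 0 rises and 0 falls by edgeR (6 with an unadjusted p below 0.05, 0 by DESeq2 and limma-voom, and 0 adjusted over the list alone). It was higher by camera (adjusted p = 0.0342), but adjusted p = 0.566 with an estimated correlation, and leaving out control library 1, control library 2, knockdown library 1 or knockdown library 2 gave 0.139, 0.0518, 0.17 and 0.073 (lowest over the alternatives 0.0344). Of 18 replication-dependent histone genes, 2 rose and 0 fell (6 rose and 0 fell adjusted over the list alone). HIST1H2AC rose from 18.0 ± 1.51 to 32.9 ± 6.77 CPM and HIST1H2BD from 8.08 ± 0.455 to 14.2 ± 3.44 CPM, the latter not past the threshold without knockdown library 2 (log2 fold change 0.54, adjusted p = 0.154). Their list was higher by camera (adjusted p = 0.0169), but adjusted p = 0.973 with an estimated correlation, and its adjusted p was 0.201 without control library 1 and 0.395 without knockdown library 2 (range 5.1e-06 to 0.395). The number of histone genes that rose was 3, 5, 6 and 1 without control library 1, control library 2, knockdown library 1 and knockdown library 2.

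**Figure D3:**
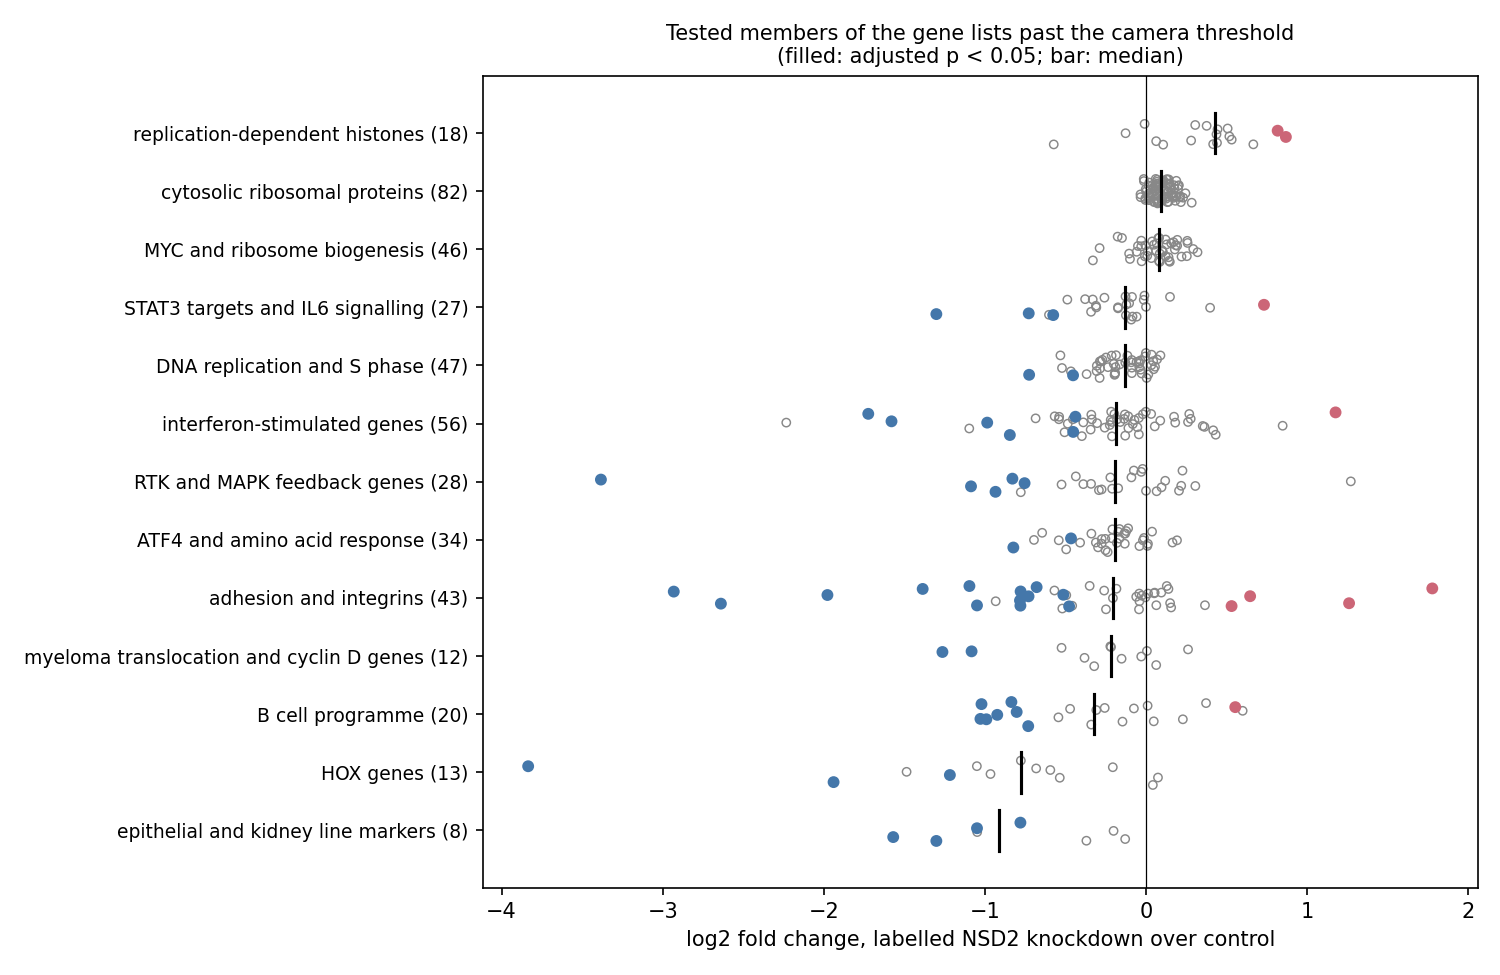
Log2 fold change (horizontal axis, libraries labelled NSD2 knockdown over control) of the tested members of the 13 gene lists that camera called with the preset correlation, with the number of members in brackets. Filled points are members past the threshold (red higher, blue lower), open points are the others, and bars are medians. The medians run from -0.91 for epithelial genes to 0.43 for histone genes, and with an estimated correlation no list was called.

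The other lists were not called by camera and held few changed members. Of 25 NF-kB targets 2 rose and 0 fell (2 rose and 1 fell adjusted over the list alone), CD83 from 0.553 ± 0.00177 to 1.5 ± 0.0675 CPM and CCL2, which was not past the threshold without knockdown library 2 (log2 fold change 1.65, adjusted p = 0.241). Of 25 extracellular matrix and mesenchymal genes 1 rose (2 adjusted over the list alone), the transcription factor gene ZEB2, 2.13-fold. The stress gene GADD45A rose from 26.2 ± 0.638 to 42.1 ± 7.95 CPM as the single call among 17 cell cycle inhibitors and among 27 p53 targets (1 rose and 1 fell in each adjusted over the list alone), and was not past the threshold without knockdown library 2 (log2 fold change 0.47, adjusted p = 0.0753). Of 32 BCL2 family and apoptosis genes 2 fell (4 adjusted over the list alone), XIAP, an inhibitor of caspases, 1.4-fold and CASP10, which lost its call without knockdown library 2 (adjusted p = 0.237). Of 20 immediate early genes 2 fell (1 rose and 4 fell adjusted over the list alone), NR4A1 from 1.01 ± 0.11 to 0.292 ± 0.00373 CPM and ATF3. The call of ATF3 was lost, as given above, only in fits that left out 1 library. The cholesterol synthesis list of 31 genes also holds genes of fatty acid synthesis and sterol transfer. In it 2 fell (4 rose and 3 fell adjusted over the list alone), neither an enzyme gene of cholesterol synthesis. The desaturase gene FADS1 fell 1.64-fold. STARD4 fell with a log2 fold change of -0.52, a call lost without knockdown library 1 (log2 fold change -0.40). Of 35 glycolysis and hypoxia genes 2 fell, also adjusted over the list alone, EPAS1, which lost its call without knockdown library 2 (adjusted p = 0.094), and ADM, which lost it without control library 2 (adjusted p = 0.104). Camera called that list lower only without control library 1 or knockdown library 2, and with an estimated correlation in neither of these fits. Counts in these lists also changed when 1 library was left out. Without control library 1, 5 BCL2 family genes, 4 NF-kB targets and 4 p53 targets rose, and 7 glycolysis and hypoxia genes and 5 cholesterol synthesis genes fell. Without control library 2 or without knockdown library 1, 5 BCL2 family genes fell, and 4 or 3 cholesterol synthesis genes rose. Without knockdown library 2, 1 NF-kB target rose, and 4 glycolysis and hypoxia genes and 4 immediate early genes fell.

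Few chromatin regulators and few genes of the NSD2 locus passed the threshold. The histone demethylase gene KDM6B fell from 19.5 ± 1.69 to 12 ± 0.912 CPM as the single call among 40 histone methyltransferases and demethylases, also adjusted over the list alone. Among 29 SWI/SNF subunits 1 fell, also adjusted over the list alone, BCL11A, from 8.37 ± 1.73 to 4.39 ± 0.785 CPM, a call lost with GC and length terms (adjusted p = 0.0505). Among 20 neighbours of NSD2 on chromosome 4, 2 fell (1 rose and 6 fell adjusted over the list alone), NAT8L, which lost its call without knockdown library 2 (adjusted p = 0.0542), and TMEM129, which lost it without control library 2 (adjusted p = 0.0509) and without knockdown library 1 (adjusted p = 0.0715). Of 14 genes of the RNA interference machinery 1 fell (1 rose and 1 fell adjusted over the list alone), TNRC6C, from 33.7 ± 4.28 to 20.4 ± 2.75 CPM. Of 13 mitochondrially encoded mRNA genes 1 fell (2 adjusted over the list alone), MT-ND4L, which overlaps MT-ND4 and lost its call without control library 2 (adjusted p = 0.0752) and without knockdown library 1 (adjusted p = 0.169). Without control library 1, 5 histone methyltransferases or demethylases and 6 neighbours of NSD2 fell.

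In 3 further lists edgeR called 0 genes, also adjusted over the list alone. Among 50 genes of G2/M and mitosis, 4 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 1 lower. Among 34 genes of the unfolded protein response 10 had an unadjusted p below 0.05, and among 46 of DNA repair 2 did, with 0 calls by limma-voom and 1 lower by DESeq2 in each. Without control library 1, 2 genes of G2/M, 3 of the unfolded protein response and 2 of DNA repair were lower, while 1 gene of G2/M and 2 of the unfolded protein response were higher. In these lists, 1 gene of G2/M was lower without control library 2, and 1 to 2 were lower without knockdown library 1. Few markers of other cell types were expressed enough to be tested. Of 6 tested T and NK cell markers, 5 tested fibroblast markers and 2 tested erythroid and platelet markers, edgeR called 0, with 4, 1 and 1 at an unadjusted p below 0.05 (3 rose and 1 fell, 1 rose, and 1 fell adjusted over the list alone). DESeq2 called 1 T and NK cell marker higher, and limma-voom called 0. The median log2 fold changes were 0.30 for T and NK cell, -0.14 for fibroblast, -0.64 for erythroid and platelet and -0.35 for myeloid markers. Of 4 tested myeloid markers 1 fell, also adjusted over the list alone, the transcription factor gene CEBPA, which was not past the threshold without control library 2 (adjusted p = 0.0529), without knockdown library 2 (0.119) or with DESeq2 (0.12). Median, mean and camera direction differed in sign for the SWI/SNF, G2/M, BCL2 family and fibroblast lists, and the medians of the first 3 lay within 0.01 of 0 and turned negative with upper-quartile and library-size scaling.

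The deposited table of the authors called 351 genes at an adjusted p below 0.05, 68 higher and 283 lower, and 340 of these were also called here, all in the same direction. The authors' values for NSD2 were a log2 fold change of -0.30 with an adjusted p of 0.933, and for CCND1 -0.50 with 0.523. Across the 10540 genes with at least 5 CPM, which are not independent replicates, the log2 fold changes of both fits had a correlation of 0.9999. The median standard error was 0.211 in the authors' table against 0.109 here. Fold changes this close point to the same libraries in both contrasts, so the shared direction is no independent evidence.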

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

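The search behind this part was chosen only after the deposited table had been seen. That table holds 17 genes with an authors' base mean over 100 and no fragment in any of the 4 libraries, a signal in values that none of the comparisons used. In 147 genes the base mean was over 100 and more than 10 times the highest of the 4 counts. LY6E had a base mean of 19230 against at most 41 fragments, and LETM1 31450 against at most 2910. Because a mean over these 4 libraries cannot exceed their highest count by so much, libraries that are not analysed here entered the authors' model. No biological explanation was tested.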

How the results depend on the processing

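The GC and length terms, and the block with these terms, were chosen only after the results were seen; all other alternatives were planned. Where tested, none of the 1018 calls changed sign under the scalings, filters, tests, block or left-out libraries, nor did any of the 294 higher and 705 lower calls in the fit with GC and length terms; 1017 were kept with RLE scaling, 987 with limma-voom, 872 with DESeq2 and 645 without knockdown library 2. The 24 genes with the largest changes and PTP4A3 kept their calls under every alternative run for them, and the epithelial and HOX lists did so under all but an estimated correlation (adjusted p = 0.566 each) and fry (0.132 and 0.209). SMARCA2 was called under none. Without a filter there were 658 higher and 1490 lower genes, NSD2 passed at -0.323 and CCND1 at -0.525, while with a minimum of 2-fold 98 higher and 384 lower remained by construction. DESeq2 called CCND1 at -0.516. Leaving out 1 library gave 173 to 682 higher and 649 to 1342 lower genes, 7 to 9 lists, and log2 fold changes of -0.502 to -0.117 for NSD2 and -0.712 to -0.309 for CCND1. With an estimated correlation 0 lists were called (0 at an unadjusted p below 0.05) and by fry 0 (7 at an unadjusted p below 0.05), against 13 by camera with the preset correlation. GC and length terms gave 366 higher and 673 lower genes, 13 lists and -0.057 for NSD2.

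The replicate block rests on numbers shared by only 2 pairs of libraries, which the labels do not say mark a batch. Differences between the numbers had a correlation of 0.236 across genes in the 2 groups (0.26 with GC and length terms), and of 0.43 among genes of at least 5 CPM. The second principal component, with 22.7% of the variance, separated the numbers. In the block fit, 340 genes were called higher and 268 lower in number 2 than in number 1. With the preset correlation of camera, number 2 was lower than number 1 in the S phase (adjusted p = 1.91e-07), ATF4 (5.52e-10), G2/M (1.1e-05), DNA repair (0.00753), B cell (0.0107) and HOX lists (0.0143) and higher in the glycolysis (1.91e-07), cholesterol (3.16e-07) and histone lists (2.31e-06). The block gave 1327 higher and 1992 lower genes, including all 1018, 13 lists, -0.317 for NSD2 (called) and -0.512 for CCND1 (called). By camera the block ended the call of the MAPK list (adjusted p = 0.0585) and called the plasma cell list (0.0422, but 0.849 with an estimated correlation). With GC and length terms it gave 2226 higher and 2307 lower genes, 14 lists, among them the MAPK list (0.0254) and the plasma cell list (0.0344), -0.069 for NSD2 and -0.477 for CCND1 (called). The cause of these shifts was not tested. The spread between 2 libraries limits the analysis: in the simulation, 56.9% of 1.5-fold changes were found.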

Other observations

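Of the tests in this part, those of duplicate removal, of neighbouring genes and of gene families were set out before their results were seen, and all others were chosen after. MHC class II genes were chosen for description after their values were seen. They include all 7 falls of the B cell list above, so they are not a separate result. Of 15 tested class II genes, with CD74 and CIITA, 13 were lower in the libraries labelled NSD2 knockdown. CIITA, the transcriptional activator of class II genes, fell from 66.6 to 32.8 CPM (log2 fold change -1.02, adjusted p = 0.00677), HLA-DPA1 from 90.0 to 47.5 CPM and HLA-DQB1 from 50.1 to 27.8 CPM. The invariant chain gene CD74 did not pass the threshold (2690 against 1940 CPM, log2 fold change -0.47, adjusted p = 0.0678), nor did HLA-DOB (0.11, adjusted p = 0.803). Fragments of related HLA genes can be assigned to one another, so the 13 genes are not 13 independent changes.

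Lysosomal genes were also described after CTSB had been seen to rise. In a list of 78 such genes, 77 were tested, 12 rose and 5 fell. CTSB (log2 fold change 1.67), PSAP (0.57) and DPP7 (1.06) rose, while IDS (-0.83) and the protease gene CTSV (-1.25) fell. The hypothesis that lysosomal genes rise as a group stays open: camera gave an adjusted p of 0.0188 with the preset correlation and 0.839 with an estimated one, and fry a p of 0.0704.

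The NSD2 count was only 19.9% lower in the libraries labelled knockdown. An exchange of a control and a knockdown library is argued against, since the lowest correlation within a group (0.9936) exceeded the highest between groups (0.9893) by 0.0043. A GC or length trend that hid a fall of at least 2-fold is also argued against, because with such terms the log2 fold change was -0.057 (95% interval -0.35 to 0.24). Duplicate removal, which may have compressed the counts of highly covered genes, stays open: of 738 genes covered at least as densely as NSD2, 76 or 10.3% (95% interval 8.2 to 12.7) changed more than NSD2, too close to the bound of 10% set beforehand, although CTSB, with 8446 fragments per kb against 2948 for NSD2, rose 3.18-fold. A weak knockdown, the biological reading that the groups offer, was not tested and stays open too. The GC and length trend at NSD2 was -0.25 in log2. The 200 longest genes had a median log2 fold change of -0.2, and 73 of them lay below NSD2. These values cannot tell a small fall of NSD2 from that trend.

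Of the 1018 called genes 70.6% were lower. The choice among the 4 scalings is argued against, since this was the lowest share over them (highest 74.2%, lowest bound of the 95% intervals 67.7). The median of all genes stayed within 0.0202 of 0 under each, so the 4 scalings differ little. When all genes were shifted alike to a median of 0.065, 556 calls were higher and 625 lower, or 52.9% lower (95% interval 50 to 55.8). Among calls of at least 2-fold, 75.6% were lower after that shift. These values follow from the shift, and whether the 4 scalings share such an error was not tested. GC content with length stays open: with such terms the share was 64.8% (95% interval 61.8 to 67.7), but 48.4% when they were first fitted without centring, which shifted the median to 0.067, and centring was chosen after that was seen. Since the shift to 0.065 alone gave 52.9%, the 48.4% cannot tell GC content and length from a shift of all genes. With the replicate block, whose numbers the labels do not call pairs, 60% of calls were lower. With the block and the centred terms 2307 genes were lower and 2226 higher, so little of the excess was left there. Low counts may add to the excess, since the share was 62.6% (95% interval 58.5 to 66.5) among called genes of at least 5 CPM, and a real excess of falls was not tested apart from these.

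Genes called lower lay beside each other more often than chance gives, with 91 adjacent, non-overlapping pairs of tested genes against 23.3 on average (14 to 33) when calls were shuffled within deciles of expression (one-sided permutation p = 1e-04, the smallest that the shuffles can give). Copies of one gene family do not account for all of it, since 60 pairs remained without family pairs, against 15.6 shuffled (permutation p = 1e-04). Nor do GC content and length, since 82 pairs were found with those terms, against 22.3 when shuffled among genes of like expression, GC content and length (permutation p = 1e-04). The hypothesis that neighbouring genes fall together, which could reflect chromatin domains, was thus met by its test, and 25 pairs were both higher, against 4.01 shuffled. The cause was not tested, and other properties shared by neighbours stay open.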
